A study of Mus musculus with 6 samples.

How the data were processed

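Total RNA of snap-frozen mouse gastrocnemius was extracted with TRI reagent and made into libraries with an Illumina TruSeq RNA kit from 1 µg, per the labels' protocols. The labels do not say whether the kit kept the strand, so reads of a gene and of an antisense partner are not told apart here. Per the submitters' processing notes, HISAT2, HTSeq, DESeq2, Cufflinks and Cuffdiff were used with the mouse build GRCm38; their versions, order and settings are not given in the sources used here. One deposited table held all 6 libraries, 25344 genes with positions, and a comparison of HSA-NRTN with WT made by the authors.

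The values per library are FPKM (reads per kilobase of gene, relative to the reads counted in genes), which the authors scaled by each library's total without a correction for composition. The table also held the authors' mean signal per gene, which is the mean of reads divided by size factors; per the file headers it carries the column name DESeq2 uses. It further held the authors' log2 fold changes with standard errors, the authors' test score (the fold change divided by its error) and the authors' p-values, raw and adjusted, of which the adjusted ones were present for 18953 genes. The columns did not name their unit. That the values are FPKM was checked from the values: together with the mean of scaled reads, 100% of the 127467 values above 0 gave whole reads within 0.01 read, and the gene lengths came out whole within 0.01 base. Of 25319 genes matched by ID to GENCODE M21 (GRCm38), 95.6% had the length of the union of their annotated exons and 97.9% the same start and end. Positions given are those of the table.

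The reads recovered in this way totalled from 27418154 to 50291845 per library. The share taken by the 10 most abundant genes was 22.6% to 23.7% in WT and 18.4% to 20.7% in HSA-NRTN. One read in a gene of 1 kilobase corresponded to 0.0199 to 0.0365 FPKM, and 3 reads to 0.0597 to 0.109 FPKM, a level below which a gene of that length can be missed in a library; this covers counting error only. Libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom from 12.1 to 33.5 over the 6 pairs); this does not show whether any 2 came from the same RNA. Xist, expressed from the inactive X chromosome of females, was at most 0.00888 FPKM, and of the 4 measured Y-linked genes, which include Ddx3y at 21.8 to 27.2 FPKM, 2 were called higher and 0 lower in HSA-NRTN (2 adjusted over the list alone; 0 and 1 with the size factors), so the libraries did not differ in the sex they came from.

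Groups and replicate numbers were taken from the labels. The test fixed before the data were examined, for normalized values, was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(FPKM + 1), on the 10755 genes with a mean of at least 1 FPKM over the 6 libraries, with no block and a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p printed for a gene comes from this test unless the authors' test or another setting is named. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Because the deposited values are normalized, a test made for raw reads was not the main test; limma-voom on the recovered reads was run as an alternative. Means are given in FPKM with the SD over 3 libraries and log2 changes with limma's SE.

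In all, 26 gene lists were fixed before the data were examined: neurturin signalling, slow and fast contractile genes, nuclear and mitochondrial respiratory genes, tricarboxylic acid cycle, fatty acid oxidation, glycolysis, mitochondrial regulators, endothelium, angiogenic factors, neuromuscular junction, denervation response, Schwann cells, neurons, macrophages, fibroblasts and matrix, adipocytes, smooth muscle and pericytes, satellite cells, red blood cells, immediate early genes, the clock, the integrated stress response, regulators of growth and atrophy, and sex-linked genes. The last served as a check and the neuronal list had 1 measured gene, so 24 lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists), which compares a list with all other genes. A further 8 lists were written after the data were seen and are used only in the closing observations. Aldoa was left out of the glycolysis list because the table gives its symbol to more than 1 identifier.

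Genes named were chosen by a rule fixed before the data were examined: 11 genes always named, the 10 genes with the largest and the 10 with the smallest log2 change among called genes without overlap between groups, and up to 3 called genes with the smallest p in each list, leaving out predicted genes, pseudogenes and immunoglobulin or T cell receptor segments from the top genes. The rule gave 96 genes. Pvalb, Hk1, Hk2, Pgm2, Dbp, Tnnc1, Myl1, Mylpf, Atp2a1, mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4l are named besides, chosen after their values were seen. The same holds for Myl2, Atp2a2, Csrp3, Myoz2, Tnni1, Tnnt1, Tpm3, Pln, Acta1, Actn2 and Tnni2. Xist and Ddx3y are named for the check of sex. A gene that the rule gave and further genes of the closing observations are not reported here. Of the 96, 31 share exon bases with another gene in GENCODE M21 and 11 share over 10% of them, 5 of these with a protein-coding gene: Mybph, Acadvl, Pgm1, Cd52 and Sqstm1. How the authors treated reads that fit several genes is not given in the sources used here, so values of near-identical genes (Ear2 and Rnase2a, the haemoglobin genes, Amd1 and Amd2) are uncertain in their division.

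The gene test was run on simulated data with the real genes' WT means and library sizes, in which 200 genes changed and 10140 were tested. Among changed genes that passed the filter, it recovered 95.1% of 61 changed 1.5-fold, 100% of 61 changed 2-fold and 100% of 60 changed 4-fold. There were 11 false calls (5.79% of calls). Changed genes that the filter left out are not counted as missed. Equal numbers rose and fell, every gene had the same spread between libraries, and the shift between scalings was absent. The simulation therefore does not test false calls that come from the scaling. In a simulation of 10168 genes with the fatty acid oxidation list raised 1.5-fold, camera called that list and 0 of the 23 others; genes were drawn independently, so this does not test the effect of correlation between genes. Alternatives planned before the data were examined were quantile normalization, no filter, a stricter filter (at least 1 FPKM in every library of a group and a mean of at least 5), no intensity trend, a pseudocount of 0.1, a test against a 1.2-fold change, the replicate number as a block, leaving out each library, and for lists an estimated correlation and fry. Scaling by the authors' size factors, limma-voom on the recovered reads and the authors' deposited test were added after the data were seen. Figures were drawn with matplotlib 3.10.9.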

Results

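RNA of the gastrocnemius, a calf muscle that in mice is made mostly of fast fibres, was sequenced in 3 libraries from wild-type mice (WT) and 3 libraries from littermates with an NRTN transgene (HSA-NRTN). The transgene is driven by the human skeletal actin promoter, which is active in skeletal muscle fibres. Neurturin, the product of Nrtn, is a secreted protein of the GDNF family that acts on neurons through the co-receptor Gfra2 and the receptor tyrosine kinase Ret. The series addresses how neurturin made by muscle relates to the oxidative metabolism of its fibres and to the type of motor neuron that supplies them. Reads counted in genes came to 27418154, 31543531 and 35243260 in the WT libraries and to 28580513, 50291845 and 30562889 in the HSA-NRTN libraries. The labels do not say how many animals stood behind each library, so the p-values measure the spread between these libraries.

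Nrtn was far higher in every HSA-NRTN library, which matches the labels of all 6 libraries. Nrtn (ENSMUSG00000039481; GRCm38 chromosome 17, 56751325 to 56757530) was measured at 3.21, 1.70 and 4.33 FPKM in the WT libraries, from 90, 55 and 156 reads. In the HSA-NRTN libraries it was measured at 178, 201 and 169 FPKM, from 5200, 10362 and 5281 reads. The mean rose from 3.08 ± 1.32 to 183 ± 16.8 FPKM (SD, n = 3 each), a ratio of 59.3. On the scale of log2(FPKM + 1) the change was 5.54 ± 0.22 (SE; limma, Benjamini-Hochberg adjusted p = 1.54e-06). The labels do not say whether the transgene carries the mouse or the human coding sequence, and the value is that of reads assigned to the mouse gene.

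Receptor transcripts for neurturin rose with it. Gfra2, the preferred co-receptor of neurturin (chromosome 14, 70890120 to 70979838), rose from 0.966 ± 0.176 to 5.80 ± 0.494 FPKM (SD, n = 3), a log2 change of 1.79 ± 0.09 (SE; limma, adjusted p = 4.88e-06). Ret (chromosome 6, 118151745 to 118197718) rose from 2.27 ± 0.266 to 4.14 ± 0.255 FPKM. Gfra1, the preferred co-receptor of GDNF (chromosome 19, 58235604 to 58455909), fell by 0.25 on the log2 scale, from 1.88 ± 0.136 to 1.43 ± 0.189 FPKM (limma, adjusted p = 0.0426). Its call was lost when WT 1, 2 or 3 or HSA-NRTN 1 or 3 was left out (limma, adjusted p from 0.0586 to 0.119). The log2 changes then ran from -0.28 to -0.18. The call was also lost with the replicate block (limma, adjusted p = 0.0735) or no filter (0.0925). With the authors' size factors Gfra1 fell by 0.43 (limma, adjusted p = 0.0021), and in the authors' deposited test by 0.69 (adjusted p = 4.97e-05). Gdnf itself, at 0.133 ± 0.0343 FPKM in WT and 0.0542 ± 0.0141 in HSA-NRTN, was below the level set for testing. Without that filter it was called lower (log2 change -0.10, limma, adjusted p = 0.0448), from 5 to 17 reads per library. In the authors' deposited test it was not past 0.05 (log2 change -1.57, adjusted p = 0.0521). Of the 4 measured genes of the fixed neurturin list, 3 rose and 1 fell, with the same counts adjusted over the list alone and with the authors' size factors. As a set, the list did not pass (camera in limma, adjusted p = 0.149), but it passed as higher with the size factors (adjusted p = 0.0326) and with limma-voom (0.0311).

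**Figure D1:**
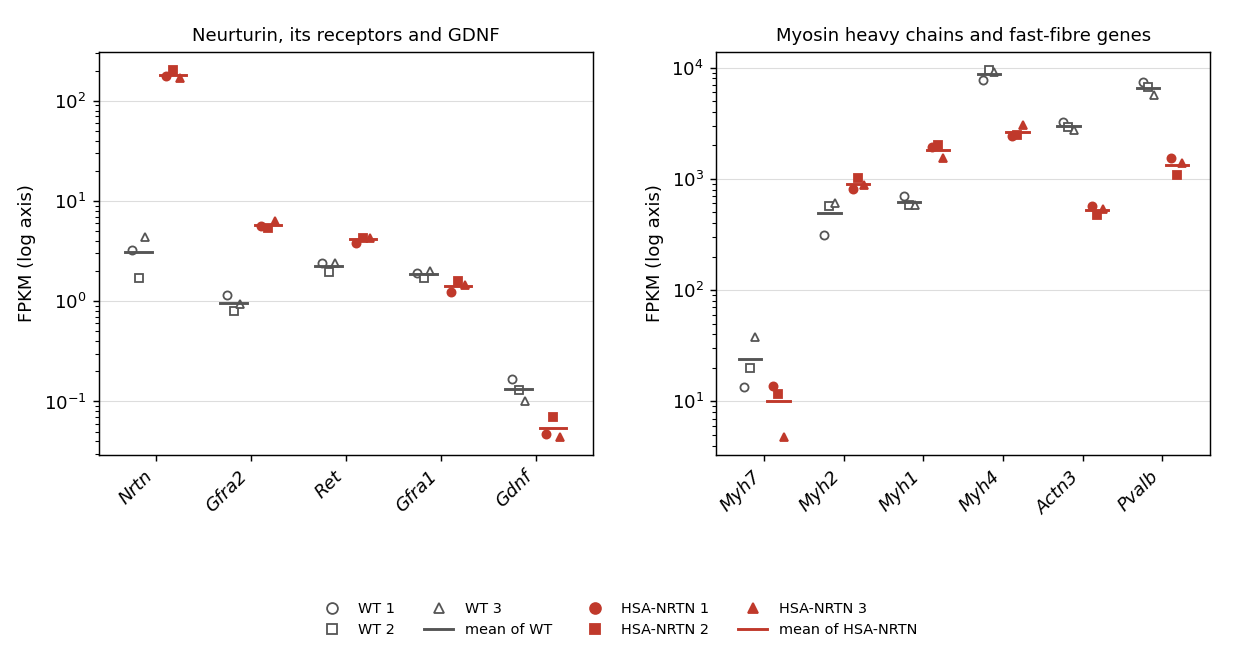
FPKM on a log axis of Nrtn, its receptors and Gdnf (left) and of the myosin heavy chains, Actn3 and Pvalb (right) in each of the 3 WT (open grey) and 3 HSA-NRTN (filled red) libraries; each symbol shape is 1 replicate number, and the bars are group means. Nrtn lay between 1.70 and 4.33 FPKM in WT and between 169 and 201 in HSA-NRTN, while Myh4 fell and Myh1 rose; the groups overlapped for Myh7.

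Over the whole transcriptome, 5731 of the 10755 tested genes differed between the groups, 4476 higher and 1255 lower in HSA-NRTN (limma, adjusted p under 0.05). With FPKM as deposited, the groups' libraries did not overlap for 6683 genes (62.1%). For a single gene, 3 against 3 gives 10% by chance, but the scaling described next shifts all genes of a library together. The 10% is therefore no yardstick for the share over genes, which was not counted with the size factors. The split between higher and lower depended on the scaling. FPKM divides by each library's total, whereas the size factors recovered from the authors' table place the HSA-NRTN libraries 0.30 lower on the log2 scale relative to WT (1.23-fold). With those size factors 2226 genes were higher and 3226 lower, and the median log2 change of all tested genes moved from 0.18 to -0.06. There were 2226 genes called higher and 1255 called lower under both scalings, and 0 with opposite calls. The scalings differ by nearly the same shift for every gene, so opposite calls were unlikely beforehand and the 0 does not measure robustness. In the authors' deposited table, 3417 genes were higher and 3365 lower among 18953 with an adjusted p. For this reason counts for gene groups below are given under both scalings, and a gene named as higher or lower was called under both unless a sentence says otherwise.

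The 10 largest increases were ranked on the log2(FPKM + 1) scale by the rule for naming genes. They were those of Nrtn, Retnla, Mucl1, Ear2, Cd74, 3 further genes of MHC class II and 2 chemokine genes. The order depends on the scale: in the authors' deposited test Mucl1 (6.75), Ccl17 (6.38) and Ear2 (5.96) rose more than Nrtn (5.60). Retnla, a secreted protein made by alternatively activated macrophages (chromosome 16, 48842551 to 48844461), rose from 19.6 ± 7.49 to 508 ± 94.1 FPKM (SD, n = 3), a log2 change of 4.67 ± 0.23 (SE; limma, adjusted p = 3.86e-06). Ear2, an RNase of eosinophils and macrophages, rose from 0.262 ± 0.0897 to 20.2 ± 2.29 FPKM. The chemokine genes Ccl6 (3.85 ± 1.94 to 54.9 ± 5.0 FPKM) and Ccl17 (0.113 ± 0.145 to 12.0 ± 5.69 FPKM) rose as well. The genes of antigen presentation on MHC class II among the 10 were picked by the size of their change and rose about alike. Cd74, the invariant chain, rose by 3.94, H2-Ab1 by 3.94, H2-Eb1 by 3.91 and H2-Aa by 3.89 on the log2 scale. In FPKM, Cd74 went from 32.5 ± 7.57 to 504 ± 42.3 and H2-Ab1 (chromosome 17, 34263209 to 34269418) from 9.49 ± 1.92 to 158 ± 12.1. Mucl1, a mucin-like gene, rose from 0.143 ± 0.0672 to 19.3 ± 5.43 FPKM. Ear2 shares sequence with Rnase2a, so how reads were divided between these genes is uncertain.

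Leaving aside unnamed genes and immunoglobulin segments, by the rule for naming genes, the 10 largest decreases were those of Mss51, Odf3l2, Smox, Mybph, Prkag3, Actn3, Mstn, Amd1, Rasd2 and Pfkfb3. Mss51, expressed mainly in skeletal muscle (chromosome 14, 20482867 to 20496901), fell from 102 ± 56.2 to 2.12 ± 0.325 FPKM (SD, n = 3), a log2 change of -4.86 ± 0.41 (SE; limma, adjusted p = 5.25e-05). Odf3l2 fell from 18.8 ± 10.6 to 0.664 ± 0.189 FPKM. Both varied widely between WT libraries and did not overlap between the groups. Smox, which oxidises spermine, fell from 111 ± 12.7 to 13.6 ± 2.95 FPKM, and Amd1, an enzyme of polyamine synthesis, from 69.9 ± 6.42 to 12.5 ± 2.06. Prkag3, the regulatory subunit of AMP-activated kinase found in glycolytic muscle, fell from 56.2 ± 3.66 to 8.61 ± 1.31 FPKM, and Mstn, which encodes the inhibitor of muscle growth myostatin, from 36.3 ± 4.26 to 6.04 ± 0.656. Pfkfb3, an enzyme that stimulates glycolysis, fell from 90.8 ± 15.6 to 17.3 ± 6.97 FPKM, Mybph, a thick-filament protein gene, from 43.3 ± 10.6 to 5.53 ± 2.54, and Rasd2, a small GTPase gene, from 27.3 ± 7.08 to 4.26 ± 0.395. The exons of Mybph overlap those of Adora1 on the opposite strand over 49.9% of their length.

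Contractile genes of fast fibres fell together, with 1 exception. Of the 14 genes of the fast contractile list, 13 fell and 1 rose under either scaling and adjusted over the list alone. Myh4, the myosin heavy chain of type IIb fibres (chromosome 11, 67238029 to 67260446), fell from 8761 ± 859 to 2635 ± 336 FPKM (SD, n = 3), a log2 change of -1.74 ± 0.12 (SE; limma, adjusted p = 2.02e-05). Actn3, the fast-fibre α-actinin, fell from 2961 ± 248 to 523 ± 47.9 FPKM, Mylk2, the myosin light chain kinase of skeletal muscle, from 364 ± 55.7 to 78.5 ± 13.9, Mybpc2 from 1662 ± 148 to 658 ± 6.46, and the calcium buffer Pvalb by 2.31 on the log2 scale. The exception was Myh1, the heavy chain of type IIx fibres (chromosome 11, 67200052 to 67224575), which rose from 621 ± 67.7 to 1829 ± 259.9 FPKM, a log2 change of 1.55. Camera called the list lower than other genes (adjusted p = 8.02e-12), and with an estimated correlation its adjusted p = 0.283.

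Slow-fibre genes moved both ways between the groups, and most rose in order over WT 1, 2 and 3. In these libraries Myl3 was at 54.2, 84.9 and 99.1 FPKM, Tnnc1 at 18.2, 28.5 and 48.0 and Myl2 at 17.0, 55.0 and 80.3. Atp2a2, Csrp3, Myh7, Myoz2, Tnni1, Tnnt1 and Tpm3 rose in the same order. Within the HSA-NRTN group, all of these except Atp2a2 were lowest in HSA-NRTN 3. Casq2, Pln and Myl6b (3.67, 3.26 and 3.26 FPKM) did not rise in order over the WT libraries. The slow list also marks the neighbouring soleus, a slow muscle that can be taken along in dissection. Whether its share differed between libraries was not tested. Of 13 measured genes of the slow contractile list, 3 rose and 2 fell, and adjusted over the list alone 3 rose and 1 fell; with the authors' size factors 1 rose and 4 fell. Camera placed the list below other genes without passing (adjusted p = 0.188), although its median was 0.05 and its mean 0.01; without WT 1 it passed (adjusted p = 0.0484). Myl3 (79.4 ± 22.9 to 134 ± 18.0 FPKM) and Casq2 (14.3 ± 3.71 to 24.7 ± 4.39) rose and Myl6b fell (3.40 ± 0.239 to 1.98 ± 0.271); the call of Myl3 ended with the size factors (limma, adjusted p = 0.0910). Myh7, the heavy chain of slow type I fibres (chromosome 14, 54970684 to 54994626), was measured at 13.6, 19.95 and 38.0 FPKM in WT and 13.7, 11.6 and 4.81 in HSA-NRTN, a log2 change of -1.155 ± 0.41 (SE; limma, adjusted p = 0.0446). The groups overlapped, and the call was lost when WT 2 or 3 or HSA-NRTN 2 or 3 was left out (limma, adjusted p from 0.0627 to 0.126; log2 change from -1.30 to -0.75), and with the replicate block (0.113) or no filter (0.124). Myh2, the heavy chain of oxidative type IIa fibres (chromosome 11, 67171027 to 67197517), rose from 497 ± 160.2 to 903 ± 101 FPKM, a log2 change of 0.92 ± 0.23 (SE; limma, adjusted p = 0.0111), and by 0.62 with the size factors, where the call ended (adjusted p = 0.0567).

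Genes of mitochondrial fuel oxidation rose nearly throughout. In the list of fatty acid uptake and oxidation 25 of 26 genes rose (26 adjusted over the list alone, 25 with the size factors). The median log2 change was 0.84, and 0.54 with the size factors. Lpl, which frees fatty acids from lipoproteins, rose from 78.4 ± 12.3 to 261 ± 19.96 FPKM (SD, n = 3), Acaa2 from 114 ± 6.75 to 257 ± 10.9 and Acadvl from 148 ± 8.71 to 293 ± 13.3. The exons of Acadvl overlap those of Dvl2 on the opposite strand over 42.9% of their length. All 18 genes of the tricarboxylic acid cycle list rose (18 adjusted over the list alone, 10 with the size factors), among them Dlst (33.2 ± 1.69 to 57.5 ± 1.56 FPKM), Dlat (57.4 ± 2.86 to 93.1 ± 3.12) and Dld (94.6 ± 2.37 to 149 ± 8.5). Of 78 nuclear genes for respiratory chain subunits, 74 rose and none fell (75 adjusted over the list alone); with the size factors 32 rose and none fell, and the median change went from 0.59 to 0.29. Atp5g3 (207 ± 4.0 to 378 ± 19.0 FPKM), Cox8a (29.4 ± 2.30 to 54.4 ± 4.01) and Ndufab1 (7.90 ± 0.155 to 12.8 ± 0.319) had the smallest p. Camera called these lists higher, with adjusted p = 1.42e-08 for fatty acid oxidation, 3.04e-05 for the tricarboxylic acid cycle and 1.17e-09 for the respiratory chain. With an estimated correlation these became adjusted p = 0.396, 0.443 and 0.443.

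Reads from the mitochondrial genome made up 9.22%, 9.55% and 9.51% of the WT libraries and 15.3%, 12.7% and 13.9% of the HSA-NRTN libraries. Of its 13 respiratory genes 8 rose (8 adjusted over the list alone), but 1 with the size factors. The 5 not called were mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4l, with WT means of 20.1, 24.7, 31.2, 3.63 and 1.08 FPKM, far below the others. They varied widely within groups (mt-Co3 at 48.5, 13.0 and 12.5 FPKM in WT), so their reads may not have been counted like those of the other genes. The list test and the share of mitochondrial reads include them as deposited. Camera did not call the list (adjusted p = 0.112), but called it with the size factors (0.0326), quantile normalization (0.0051), the stricter filter (0.0362), the replicate block (0.0344), limma-voom (0.0189) and without HSA-NRTN 3 (0.0414). The calls of mt-Co1 (11217 ± 369 to 17896 ± 1507 FPKM), mt-Cytb (17468 ± 679.9 to 25734 ± 2130) and mt-Nd2 (11187 ± 72.8 to 16385 ± 1783) ended with the size factors (limma, adjusted p = 0.0515, 0.167 and 0.186).

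Glycogen breakdown and glycolysis went mostly the other way. Of 23 measured genes 16 fell and 6 rose (16 and 6 adjusted over the list alone, 17 and 3 with the size factors). Phka1, a subunit of phosphorylase kinase, fell from 203 ± 22.1 to 64.7 ± 5.11 FPKM (SD, n = 3), Pgm1 from 520.0 ± 31.7 to 245 ± 6.53 and Gpd1 from 226 ± 19.7 to 117 ± 2.30. Those that rose under both scalings were Hk1, Hk2 and Pgm2. Camera called the list lower (adjusted p = 8.58e-07), and with an estimated correlation its adjusted p = 0.283.

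**Figure D2:**
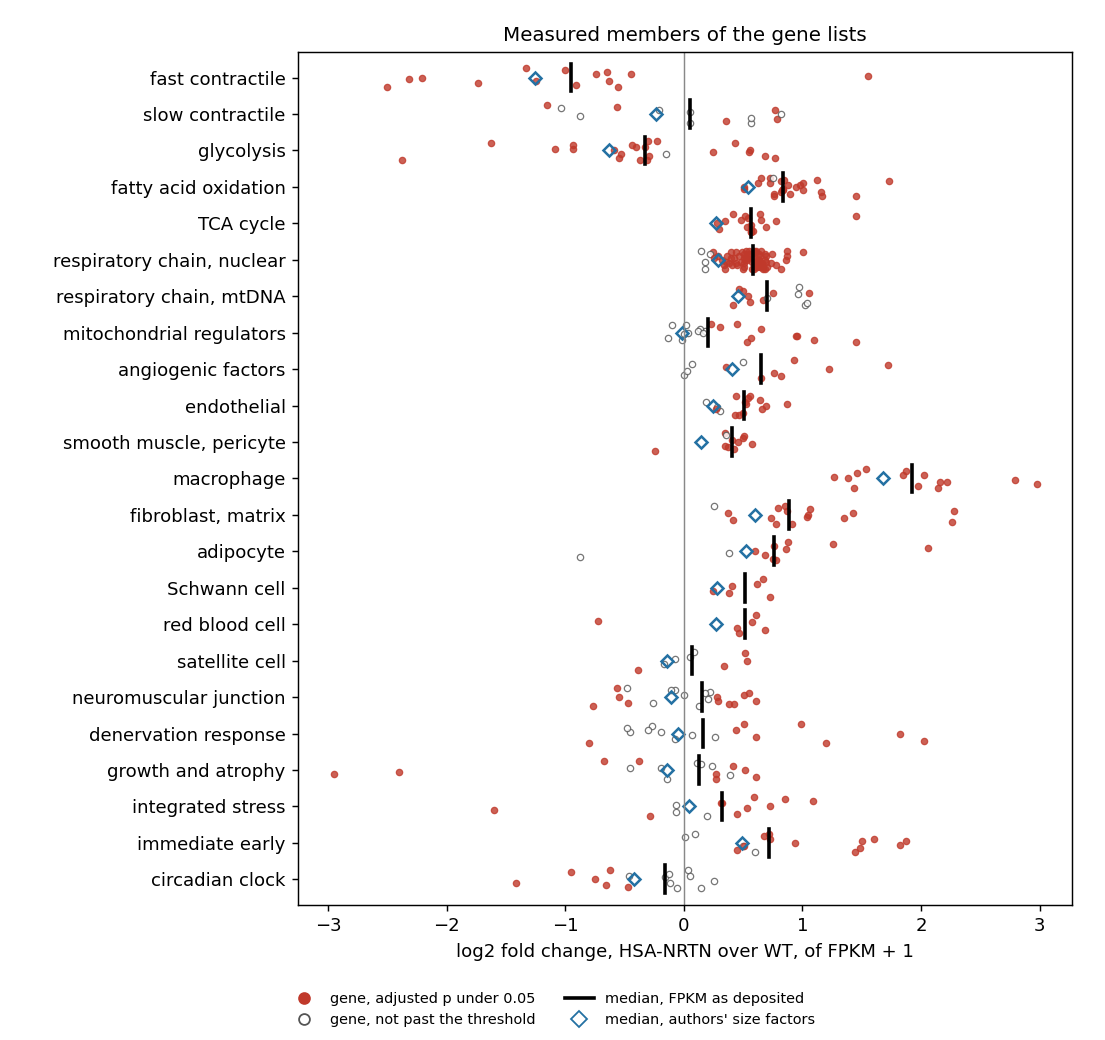
Log2 fold change of FPKM + 1, HSA-NRTN over WT (x axis), of every measured member of 23 gene lists (y axis); filled red points are genes with an adjusted p under 0.05 in limma and open points are the others. Black bars are list medians with FPKM as deposited and blue diamonds the medians with the authors' size factors. The macrophage median lay at 1.92 and the fast contractile median at -0.96, and the slow contractile median moved from 0.05 to -0.24 with the size factors.

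Among 20 regulators of mitochondrial genes 10 rose and none fell (10 adjusted over the list alone), while with the size factors 6 rose and 4 fell. Ppara, a receptor that controls fatty acid oxidation genes, rose from 2.34 ± 0.245 to 8.29 ± 2.26 FPKM, Perm1 from 70.0 ± 9.93 to 149.9 ± 12.0 and Sirt3 from 3.41 ± 0.327 to 5.54 ± 0.390 (SD, n = 3). Ppargc1a, the coactivator PGC-1α (chromosome 5, 51454250 to 51567726), rose from 7.98 ± 1.68 to 17.4 ± 8.96 FPKM, a log2 change of 0.94 ± 0.29 (SE; limma, adjusted p = 0.0259). Its call ended with the size factors (log2 change 0.67; adjusted p = 0.0847) and without WT 1 or WT 2 (limma, adjusted p = 0.0724 and 0.0719; log2 change 0.88 and 0.86). The size of the change leaned on HSA-NRTN 3 (27.6 FPKM, against 13.6 and 10.9 in the other 2), and without it was 0.57, with the call kept. Camera did not call the list (adjusted p = 0.368).

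Genes of blood vessels and of their growth factors rose in part. Vegfa, the main angiogenic factor of muscle (chromosome 17, 46016993 to 46032369), rose from 47.5 ± 5.54 to 112 ± 7.24 FPKM (SD, n = 3), a log2 change of 1.22 ± 0.10 (SE; limma, adjusted p = 3.78e-05). Vegfb rose from 57.4 ± 4.27 to 102 ± 3.48 FPKM and Angptl4 from 2.06 ± 0.378 to 9.31 ± 2.90. Of 11 measured angiogenic factors 7 rose and none fell (7 adjusted over the list alone, 6 with the size factors; camera, adjusted p = 0.0857, and 0.0174 with the size factors). Of 16 endothelial markers 13 rose and none fell (13 adjusted over the list alone, 7 with the size factors), among them Eng (12.5 ± 1.34 to 23.7 ± 1.72 FPKM), Flt1 (5.70 ± 0.674 to 9.83 ± 1.03) and Pecam1 (12.9 ± 1.11 to 20.8 ± 2.40). Camera called the endothelial list higher (adjusted p = 0.0189), and with an estimated correlation its adjusted p = 0.677. Without WT 1 this call was lost as well (camera in limma, adjusted p = 0.0581). Of 11 markers of smooth muscle and pericytes 9 rose and 1 fell (10 and 1 adjusted over the list alone, 2 and 1 with the size factors; camera, adjusted p = 0.176, and 0.0443 with quantile normalization). Pdgfrb rose from 7.74 ± 0.536 to 10.998 ± 0.785 FPKM and Tagln from 14.6 ± 1.76 to 22.3 ± 3.05; Smtn went from 20.5 ± 2.33 to 29.6 ± 1.76, a call that ended with the size factors (limma, adjusted p = 0.0843).

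Markers of macrophages and other leukocytes rose in full. All 14 rose under either scaling and adjusted over the list alone, with a median log2 change of 1.92. Cd52, a leukocyte surface protein, rose from 0.486 ± 0.0633 to 10.7 ± 1.19 FPKM (SD, n = 3), Lyz2, the lysozyme of myeloid cells, from 27.9 ± 4.62 to 198 ± 9.94, and Adgre1, which encodes the macrophage marker F4/80, from 2.09 ± 0.339 to 12.6 ± 0.80. Camera called the list higher (adjusted p = 1.30e-08), and with an estimated correlation its adjusted p = 0.396. Fibroblast and matrix genes rose in 15 of 16 cases (15 adjusted over the list alone, 13 with the size factors), including Fn1 (12.7 ± 1.38 to 64.6 ± 6.64 FPKM), Postn (1.73 ± 0.358 to 12.3 ± 1.84) and Col6a1 (28.5 ± 4.28 to 77.7 ± 3.04). Camera called them higher (adjusted p = 3.45e-05; adjusted p = 0.443 with an estimated correlation). Of 11 adipocyte markers 9 rose and none fell (9 rose and 1 fell adjusted over the list alone, 4 and 1 with the size factors; camera, adjusted p = 0.176, and 0.0174 with the size factors), with Cfd from 40.3 ± 12.1 to 175 ± 71.5, Fabp4 from 32.3 ± 0.565 to 60.3 ± 11.4 and Pck1 from 3.80 ± 1.22 to 10.6 ± 3.34 FPKM. Of 6 red blood cell transcripts 5 rose and 1, Bpgm, fell (5 and 1 adjusted over the list alone; camera, adjusted p = 0.708). With the size factors 0 rose and Bpgm alone fell (limma, as for all calls), and Hba-a2 (22.8 ± 5.45 to 34.8 ± 0.450 FPKM) and Hbb-bs (75.8 ± 17.9 to 111 ± 3.71), near-identical in sequence to their sister genes, were at adjusted p = 0.0802 and 0.166. Without WT 2 the log2 change of Hbb-bs went from 0.58 to 0.37.

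**Figure D3:**
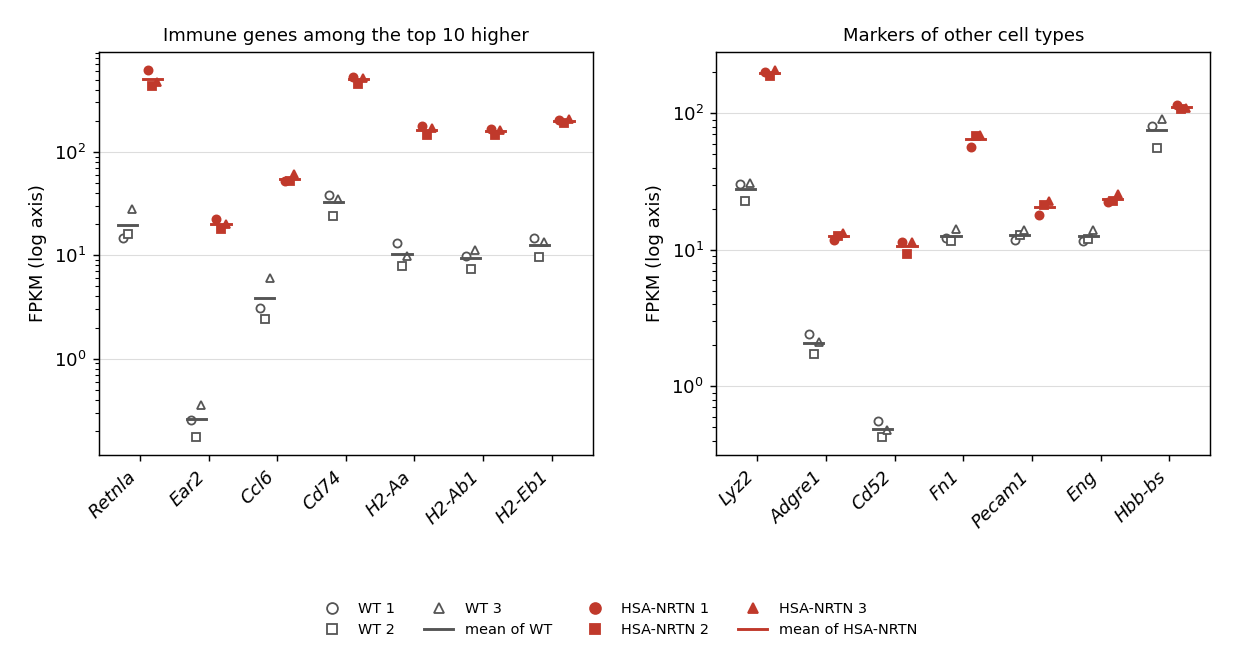
FPKM on a log axis in each of the 3 WT (open grey) and 3 HSA-NRTN (filled red) libraries of immune genes among the largest increases (left) and of markers of macrophages and leukocytes (Lyz2, Adgre1, Cd52), matrix (Fn1), endothelium (Pecam1, Eng) and red blood cells (Hbb-bs) (right); bars are group means. The groups did not overlap for any gene shown; Cd74 went from 32.5 to 504 FPKM and Hbb-bs from 75.8 to 111, the latter not called with the authors' size factors.

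Genes of nerve and synapse changed in part. All 6 measured Schwann cell markers rose (6 adjusted over the list alone, 3 with the size factors), with Mbp from 2.73 ± 0.282 to 5.18 ± 0.423 and Pmp22 from 16.3 ± 1.73 to 26.7 ± 4.68 FPKM (SD, n = 3). Camera did not call the list (adjusted p = 0.112), but did with the size factors (0.0326), no filter (0.0068) and limma-voom (0.0320). Of the neuronal list 1 gene was measured, Uchl1, at 1.52 ± 0.596 FPKM in WT and 1.99 ± 0.496 in HSA-NRTN, which was not past the threshold (limma, log2 change 0.26, adjusted p = 0.239); without WT 3 it was called higher (0.44, adjusted p = 0.0393), and without WT 1 or HSA-NRTN 2 the change was 0.13 in either case. At the neuromuscular junction 7 of 20 genes rose and 4 fell (7 and 5 adjusted over the list alone, 3 and 8 with the size factors). Chrna1, a subunit of the acetylcholine receptor, rose from 2.84 ± 0.25 to 4.86 ± 0.541 FPKM, while the subunit gene Chrnb1 fell from 10.1 ± 0.526 to 6.52 ± 0.900 and Ache, the acetylcholinesterase gene, from 8.16 ± 1.06 to 4.36 ± 0.389. Of 16 genes that rise after loss of the nerve 7 rose and 1 fell (7 and 1 adjusted over the list alone, 6 and 4 with the size factors). Mt1, a metallothionein gene, rose from 3.01 ± 0.356 to 13.3 ± 2.50 FPKM and Ampd3 from 2.72 ± 0.550 to 7.51 ± 1.11, and Myh8, the perinatal myosin heavy chain, fell from 109 ± 3.93 to 62.2 ± 5.52. Camera did not call the junction list (adjusted p = 0.188, and 0.0094 with the stricter filter, where it was called) or the denervation list (adjusted p = 0.658), and placed both below other genes although their medians were 0.15 and 0.17 and their means 0.02 and 0.33.

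Clock genes fell in part and none rose. Of 15 measured genes 6 fell (6 adjusted over the list alone, 10 with the size factors), among them Bhlhe41 (12.8 ± 0.677 to 4.20 ± 0.442 FPKM), Tef (33.8 ± 1.09 to 21.6 ± 1.05) and Hlf (2.87 ± 0.185 to 1.31 ± 0.149; SD, n = 3). Dbp, a direct output of the clock, fell by 0.95 on the log2 scale. Camera called the list lower (adjusted p = 8.23e-06), and with an estimated correlation its adjusted p = 0.171. The labels give no time of day at which muscles were taken.

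Immediate early genes, which also respond to handling of tissue, rose in 12 of 16 cases (13 adjusted over the list alone, 7 with the size factors). Camera did not call them (adjusted p = 0.112), but did with the size factors (0.0081), quantile normalization (0.0051), no filter (0.0221), limma-voom (0.0081) and without WT 3 (0.0159) or HSA-NRTN 3 (0.0056). Junb rose from 3.79 ± 0.656 to 17.8 ± 9.66 FPKM, Ier2 from 5.68 ± 1.26 to 11.9 ± 3.06 and Maff from 1.39 ± 0.422 to 2.91 ± 0.138 (SD, n = 3). Of 13 genes of the integrated stress and unfolded protein responses 8 rose and 2 fell (8 and 2 adjusted over the list alone, 6 and 4 with the size factors; camera, adjusted p = 0.538). Those that rose included the endoplasmic reticulum chaperone genes Pdia4 (6.66 ± 0.759 to 15.3 ± 2.17 FPKM) and Hsp90b1 (33.6 ± 3.11 to 62.2 ± 12.3) and the transcription factor Ddit3 (6.08 ± 0.646 to 9.66 ± 0.794).

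Regulators of muscle mass moved both ways. Of 16 measured genes 5 rose and 4 fell (7 and 4 adjusted over the list alone, 2 and 7 with the size factors; camera, adjusted p = 0.0973, and 0.0479 with the stricter filter). Besides Mstn and Smox, the autophagy receptor gene Sqstm1 fell, from 164 ± 5.98 to 102 ± 2.03 FPKM (SD, n = 3). The median of this list was 0.13 and its mean -0.26, and camera placed it below other genes. Of 8 satellite cell markers 3 rose and 1 fell (3 and 1 adjusted over the list alone, 2 and 3 with the size factors; camera, adjusted p = 0.637, below other genes although the median was 0.07 and the mean 0.11). Sdc4 rose from 10.9 ± 0.0240 to 15.9 ± 0.197 FPKM and Vcam1 from 0.690 ± 0.120 to 1.47 ± 0.416, and Cdh15 fell from 6.42 ± 0.988 to 4.65 ± 0.177. With quantile normalization the change of Vcam1 went from 0.53 to 0.21 and its call ended (limma, adjusted p = 0.185).

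Of the 24 lists tested, camera called 9 with its preset correlation. Other splits of the 6 libraries into 3 and 3 gave from 6 to 11 calls by the same test. The number of lists called therefore does not tell the real groups from other groupings. With an estimated correlation it called 0, with 3 at an unadjusted p under 0.05 (fast contractile, glycolysis and clock). The fry test, which asks whether a list moves one way without comparing it with other genes, called 19. It was run with FPKM as deposited, where the median log2 change of all tested genes was 0.18. Lists that fry called higher can therefore owe part of this to the scaling.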

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

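Scaling by the authors' size factors, limma-voom on the recovered reads and the authors' deposited test were chosen after seeing the data; the other alternatives were planned. The number of changed genes stayed within 1.5 times of 5731 except with the stricter filter (2960 of 5395 tested, 2023 of them higher; fewer genes entered the test) and against a 1.2-fold change (2243, with 1808 higher and 435 lower; the test asks for a larger change). Leaving out each library gave from 4460 to 5694. The split by direction followed the scaling: higher and lower genes numbered 2377 and 2889 with quantile normalization, 2226 and 3226 with the size factors, 2351 and 3303 with limma-voom, and 2189 and 3032 in the authors' deposited table over the same 10755 genes. By construction these 4 set the typical gene, not the library total, equal between libraries; which of the scalings is closer to RNA per fibre was not tested. The Nrtn change lay between 5.27 and 5.94 in all its alternatives. Camera called 9 lists, and 14 with quantile normalization, 14 with the stricter filter, 15 with the size factors, 15 with limma-voom and 0 with an estimated correlation (3 at an unadjusted p under 0.05); fry called 19. Except for the estimated correlation, which allows for genes of a list varying together, and the scaling, the cause was not tested.

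With the replicate block 5521 genes were called (4309 higher and 1212 lower) and 10 lists. Libraries with the same number did not deviate together (correlations 0.08, -0.17 and 0.19 over genes), and WT 1 and WT 2 correlated best with another number, so the numbers were not taken as pairs. Of 95 named genes tested, 16 lost their call in at least 1 alternative, 9 of them with the size factors and 3 (Gfra1, Myh7 and Ppargc1a) without 1 of the libraries; no call of a named gene or list changed direction. Without a library the endothelial list lost its call, and the slow contractile, immediate early, mitochondrial respiratory and angiogenic lists gained a call. Gdnf, with 5 to 17 reads per library, was left out by the filter and was called lower without it (limma, adjusted p = 0.0448). The authors' deposited test did not call it (adjusted p = 0.0521). A test on raw counts, planned for a count table, was not run because the values are normalized, and camera has no form of the 1.2-fold test.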

Other observations

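The gene lists and single genes of this and the next paragraph were chosen after the data were seen, so they describe and do not test. All 7 measured genes of MHC class II presentation rose under both scalings, with log2 changes from 2.50 to 3.94. H2-DMa went from 1.36 ± 0.0724 to 22.7 ± 2.46 FPKM and H2-DMb1 from 0.706 ± 0.164 to 14.1 ± 1.10 (SD, n = 3). All 11 measured genes of myeloid cells in type 2 inflammation rose (10 with the size factors, where Ccl24 was not called), among them Mgl2 (2.33 ± 0.604 to 28.0 ± 3.15 FPKM) and Alox15 (0.148 ± 0.136 to 6.78 ± 0.9996). Siglecf, a marker of eosinophils, was at 0.0454 ± 0.0296 FPKM in WT and 1.603 ± 0.324 in HSA-NRTN, below the level set for testing. Ighm, the heavy chain of IgM, went the other way, from 76.5 ± 10.1 to 9.47 ± 1.6004 FPKM (log2 change -2.89 ± 0.13, SE; limma, adjusted p = 2.91e-06). Igkc, the light chain constant region, rose from 1.09 ± 0.596 to 6.50 ± 1.88 FPKM, and the B cell gene Cd79a was at 0.237 ± 0.1304 and 0.377 ± 0.0338. The level of Ighm in WT muscle was thus far above that of the other B cell transcripts.

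Some transcription factors of fast and type IIb fibres fell under both scalings, with Mafa from 26.8 ± 3.45 to 6.42 ± 0.647 FPKM, Maf from 42.9 ± 1.99 to 16.0 ± 0.45048, and Tbx15 and Sox6 by 0.82 and 0.80 on the log2 scale (SD, n = 3). In polyamine metabolism 4 of 9 genes fell and 2 rose (6 and 1 with the size factors). Besides Smox and Amd1, Odc1, the first enzyme of synthesis, fell from 26.9 ± 2.02 to 9.71 ± 0.556 and Sms from 21.1 ± 0.603 to 8.52 ± 0.317, while Sat1, which acetylates polyamines for export, rose from 5.48 ± 0.520 to 11.9 ± 0.791 FPKM. Of the 7 subunits of AMP-activated kinase 3 fell and 3 rose (3 fell and 0 rose with the size factors, limma). Those that fell were Prkag3, Prkab2 (120.5 ± 7.04 to 43.1 ± 1.68 FPKM) and Prkaa2 (59.0 ± 2.04 to 43.8 ± 2.14).

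Among the tests of explanations that follow, those of lymph node, blood, a lower fibre share and the scaling were chosen after the result was seen; the test of dilution and the counts of splits were written before their results, although the list of shared structural genes was drawn up after the fast list had been seen. The first pattern is the rise of macrophage and MHC class II transcripts. Lymph node taken along in dissection would bring B and T cell transcripts at levels near those of class II, but of the 8 B cell markers listed, which hold no immunoglobulin gene, the highest mean in HSA-NRTN was 0.5364 FPKM, and of 8 T cell markers the highest was Trac at 0.897 FPKM (1.36 in HSA-NRTN 3); Igkc, outside the list, rose to 6.50 FPKM, so a small share of lymphocytes is not ruled out. More blood left in the muscle would raise haemoglobin at least as much, but its median log2 change was 0.5939, which was 1.33 below that of the macrophage list. A lower share of fibre RNA would raise markers of every other cell type alike. The lowest change in the macrophage list lay 0.3962 above the highest in the endothelial list. The fibroblast and adipocyte lists reached 2.28 and 2.06, above the lowest macrophage change of 1.26, so this comparison holds for endothelium only. Medians were 1.92 for macrophages, 0.89 for fibroblasts and 0.51 for endothelium. The rise was thus not even, but a part played by a lower fibre share is not ruled out. A larger number of macrophages and related myeloid cells in HSA-NRTN muscle, or a change in their state, may therefore be behind the pattern; these were not tested apart, and the time of day and handling of the muscles, which the labels do not give, stay open.

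The second pattern is the fall of fast contractile transcripts. If RNA of other cells had diluted fibre RNA, structural genes shared by all fibre types would fall about as much. Their median log2 change was -0.01919 over 18 genes, 0.94 above that of the fast list, with an interquartile range of 0.50; 7 of them fell and 2 rose (10 and 1 with the size factors, median -0.32). The 18 genes ran from -0.96 to 1.43, with Acta1 going from 17192 to 12129 FPKM and Actn2 from 277 to 736. Whether all fibre types express them alike was not tested, so their median is a rough guide. Dilution alone thus falls short for Myh4 (-1.74) and Actn3 (-2.50), which fell by more than any of the 18. For genes of the fast list that fell less, such as Tnni2 (-0.45), dilution is not ruled out. A shift of fibres from type IIb towards type IIx transcripts is a candidate explanation for the heavy chains. On the log2 scale Myh4 fell by 1.74 and Myh1 rose by 1.55, but in FPKM the exchange was not balanced. Myh4 fell from 8761 to 2635 FPKM, while Myh1 rose from 621 to 1829 and Myh2 from 497 to 903. Myl1 (4447 to 2220 FPKM), Mylpf (4835 to 2562) and Atp2a1 (9791 to 5852), also of the fast list, fell as well. The shift would not explain their fall if both fibre types express them alike, which was not tested. No count of fibres by type was analysed here, and a change of promoter activity within fibres cannot be separated from a change in fibre number in whole-muscle RNA.

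The third pattern is the rise of oxidative metabolism transcripts, which could come from scaling by library totals, since that raises HSA-NRTN by 0.30 on the log2 scale. With the authors' size factors, which remove that shift, the median of the nuclear respiratory genes went from 0.59 to 0.2886 (quartiles 0.16 and 0.36), above 0 by more than its interquartile range. The genes called higher went from 74 to 32 of 78, since the smaller change left fewer past the threshold. Scaling by totals thus falls short as the whole cause if the size factors hold, and which scaling is closer to RNA per fibre stays open. Whether the remaining rise reflects more mitochondria per fibre or more transcripts per mitochondrion was not tested.

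Other splits of the 6 libraries into 3 and 3 are too few (10) for a share under 0.05. The real split gave 5731 genes, 1 of 10 splits with as many. The highest other split gave 0 in limma (35 to 331 genes at an unadjusted p under 0.05). Every other split puts WT and HSA-NRTN libraries into the same group, which widens the spread within groups. Few calls were therefore foreseeable there, and the 0 does not measure chance. For lists tested by camera with the preset correlation, the real split gave 9 and the highest other 11, and 5 of the 10 splits gave at least 9. The number of lists called thus does not set the real split apart.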
